A study of Danio rerio with 16 samples.

How the data were processed

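Whole zebrafish larvae of the wild-type AB strain were exposed from about 1 to 72 hours post fertilization to 0, 4, 40 or 400 ppb perfluorohexanoic acid (PFHxA), a short-chain perfluoroalkyl acid, per the labels. Total RNA came from pools of 45 to 50 fish, with 4 replicates per dose and 1 single-colour (Cy3) Agilent array per replicate, 16 arrays in all. The labels conflict in places. The treatment text names PFbA and the design text gives the highest dose as 40 ppb, whereas titles and characteristics give PFHxA and 400 ppb, which were used here. The labels name Feature Extraction 12.0, but the file headers name version 11.5.1.1 for slides 1, 3 and 4 and version 11.0.1.1 for slide 2.

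Per the file headers, the spot files hold fluorescence intensity: raw and background signals in scanner units, and a processed signal that the authors' image software had corrected for background. The deposited series values are intensity as well, on the linear scale, and their ratio to the processed signal was checked and lay between 0.995 and 1.00. The spot files also carry other values, the flags of the image software per the file headers, which mark outlying spots and spots well above background. The authors deposited lists of probes for each dose, with log2 ratios and signed folds (an other unit), under human gene symbols. The normalization and the p threshold behind those lists are not stated.

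The values analysed here were the log2 processed signal minus the array's 75th percentile. Spots with an outlier flag were left out and the spots of a probe were averaged. Of 128291 probes, 107040 that were well above background on at least 4 of the 16 arrays were tested. Probes were named by RefSeq accession alone, which gave 39952 probes (31.1%) and 13547 gene symbols. No probe was named by sequence, so 88339 probes stayed without a name.

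Dose groups were compared with limma 3.58.1 in R 4.3.3, with 1 mean per dose and a spread shared by all 16 arrays. The tests were each pair of doses, any dose against 0 ppb and a slope over the ranked doses. The Benjamini-Hochberg adjusted p was held against 0.05 within each test. All p of single probes come from limma and are two-sided. Gene lists fixed before the data were examined numbered 45, with 9 to 79 measured members among 13276 genes, each gene by its brightest probe. They were tested with limma's camera at a preset correlation between genes of 0.01, beside camera with an estimated correlation and fry. The files were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and data.table (version 1.17.8), and plots were drawn with matplotlib 3.10.9.

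Genes to be named were chosen by a rule set beforehand. It takes, per dose and direction, the 10 largest log2 changes that pass the threshold, filled up with the smallest unadjusted p where fewer pass. It adds at most 4 members per list, namely those that pass or else the 2 with the smallest p, then the 5 smallest p for the trend in each direction and for any dose, and the 5 highest and 5 lowest folds per dose in the authors' deposited table. fkbp5, klf9 and lpin1a at every dose were added after their values were seen. Some genes that the rule chose are not reported here.

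The alternatives tried were normexp background correction with an offset of 50, quantile normalization, the deposited series values, no filter or a filter on all arrays, outlier spots kept, the replicate number as a fixed or random block, a variance trend with robust fitting, array weights, the compared groups alone, and each array left out in turn. Replicate number and slide are the same thing in these files, so a separate block for slide was not run. Fits without the 40 ppb replicate 1 array in every comparison, and the block without it, were added after its negative controls were seen.

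The procedure was tested on simulated data with 200 changed probes of 105872 at 400 ppb. With the spread of all 16 arrays it recovered 0 of the 2-fold changes and 79 (39.5%) of the 4-fold changes, with 5 false calls. With the spread left after removing the 40 ppb replicate 1 array and with slides as a block, it recovered 136 (68%) and 184 (92%). Only the spread came from that fit: 16 arrays without slide effects were simulated and fitted without a block. These counts therefore do not give the recovery of the blocked fit itself. A list shifted by a log2 of -0.25 was called in 20 of 20 simulated rounds by camera at both correlations and by fry. In these rounds the genes varied independently of each other and had the smaller of the spreads above. The rounds therefore do not show how well the list tests find a shift among correlated genes. The number of arrays limits the precision of all values.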

Results

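The arrays measured transcripts in whole larvae at 72 hours post fertilization, with 4 replicates at each of 0, 4, 40 and 400 ppb PFHxA. The 4 arrays with the same replicate number shared a slide, and each dose took the same position on every slide. On the arrays other than 40 ppb replicate 1, between 74.4% and 86.3% of spots were well above background. On the 40 ppb replicate 1 array this share was 98.4%, and its negative controls had a median of 1317 scanner units against 29.5 to 57 on the others. Its correlation with the other arrays across probes was at most 0.609, while every other pair of arrays reached at least 0.950. It stayed in all comparisons as planned. For the named lists whose call ended without it, the value without it is given. Log2 differences are given with the standard error (SE) from limma or with the standard deviation (SD), and n = 4 per group unless stated.

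**Figure D1:**
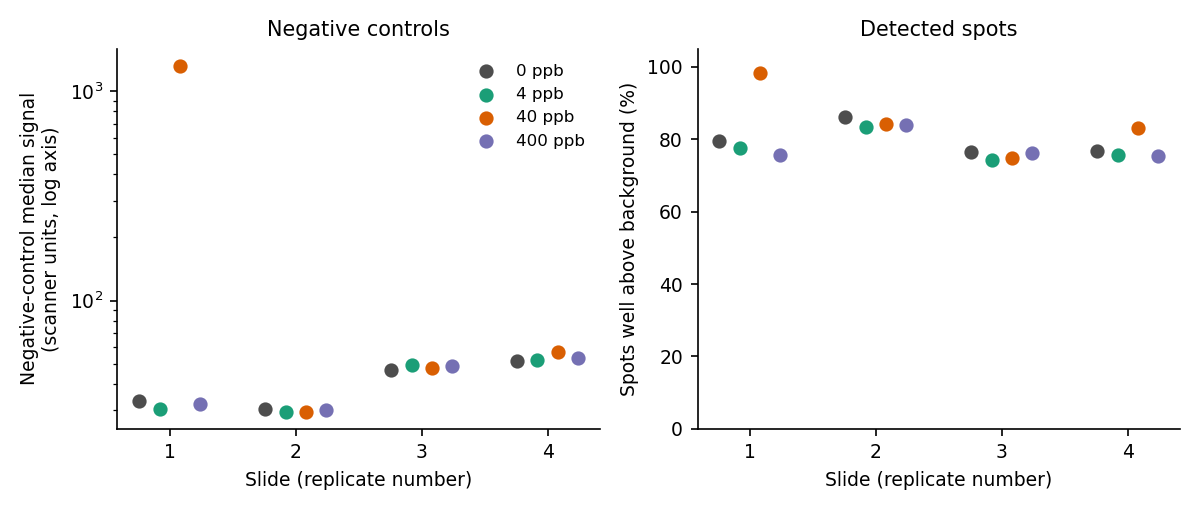
Median signal of the negative controls (scanner units, log axis) and share of spots well above background (%), per array, by slide and coloured by dose. The 40 ppb replicate 1 array, at 1317 and 98.4%, lies above the other arrays in both panels.

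The comparison of 4 ppb with 0 ppb asked whether the lowest dose altered transcripts. Genes of cholesterol synthesis were lower in 23 of 25 cases, with a median log2 difference of -0.13, and their median was lower on all 4 slides. The list was called by camera (adjusted p = 0.00136), but not with an estimated correlation (adjusted p = 0.711). Its members with the smallest p were stard4, a sterol transfer protein (-0.19, SE 0.24; -0.12 without 0 ppb replicate 2), and sc5d, a desaturase late in the pathway (-0.25, SE 0.33; -0.16 without 4 ppb replicate 2). Xenobiotic metabolism genes were lower in 34 of 37 cases (median -0.10, camera adjusted p = 0.0149, estimated-correlation adjusted p = 0.532), also on all 4 slides. The conjugating enzyme ugt5a1 differed by -0.78 (SE 0.66) and was above background on 2 of 4 arrays at this dose.

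Fatty acid and triglyceride synthesis genes were lower in 16 of 20 cases at 4 ppb (median -0.07, camera adjusted p = 0.00122, estimated-correlation adjusted p = 0.360). They included the desaturase fads2 (-0.41, SE 0.31; -0.16 without 4 ppb replicate 1) and lpin1a, a phosphatidate phosphatase (-0.52, SE 0.21). Genes of estrogen, androgen and gonadal steroids were lower in 27 of 32 cases (median -0.14, camera adjusted p = 0.00122, estimated-correlation adjusted p = 0.711), among them the yolk protein vtg5 (-0.35, SE 0.22). Intestinal genes were lower in 24 of 30 cases (median -0.12, camera adjusted p = 0.00121, estimated-correlation adjusted p = 0.360). Exocrine pancreas genes were lower in 20 of 21 cases (median -0.19, camera adjusted p = 0.000733, estimated-correlation adjusted p = 0.360), with ptf1a at -0.26 (SE 0.27) and ela2 at -0.47 (SE 0.50; -0.20 without 4 ppb replicate 2). Their median was -0.67 on slide 2 and 0.43 on slide 3, so the slides did not share a direction. Ribosomal protein genes were higher in 77 of 79 cases (median 0.10, camera adjusted p = 1.19e-05, estimated-correlation adjusted p = 0.966), such as rpl3 at 0.21 (SE 0.56). The log2 signal of rpl3 was 4.85 on the 40 ppb replicate 1 array and between 7.85 and 8.38 on all others, so that array widened this SE. Quantile normalization turned the ribosomal median to -0.01, and the median of the skeletal muscle list from 0.05 to -0.03. With normexp background correction the medians were nearer 0 for estrogen and androgen genes (-0.04), xenobiotic metabolism (-0.05), intestine (-0.07), exocrine pancreas (-0.10), pigment cells (-0.09) and pituitary hormones (-0.05; -0.08 before).

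The other lists called at 4 ppb were pigment cells (23 of 33 lower, camera adjusted p = 0.00136), pituitary and hypothalamic hormones (31 of 35 lower, camera adjusted p = 0.0124) and photoreceptors (46 of 57 lower, camera adjusted p = 0.0203). The hatching gland (6 of 9 higher, camera adjusted p = 0.00326), skeletal muscle (37 of 58 higher, camera adjusted p = 0.00667) and erythroid lists (21 of 32 higher, camera adjusted p = 0.0133) were called in the other direction. The estimated-correlation adjusted p of these lists lay between 0.360 and 0.975. In the pituitary list the gonadotropin subunit lhb had -1.12 (SE 1.06; -1.74 without 0 ppb replicate 4), and in the erythroid list the adult globin hbba1 had 0.84 (SE 1.04; 0.32 without 4 ppb replicate 1), both near background. In the hatching gland list the hatching enzyme he1.1 had 0.49 (SE 0.44; 0.20 without 0 ppb replicate 2), and in the muscle list, whose median was higher on 2 of 4 slides, srl had 0.33 (SE 0.37; 0.19 without 0 ppb replicate 3).

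The 40 ppb replicate 1 array enters the 4 ppb comparison through the shared spread, and 6 of the 13 lists were called with and without it. Without it, the camera adjusted p was 0.0604 for fatty acid and triglyceride synthesis, 0.0573 for estrogen and androgen genes, 0.0573 for intestine, 0.0573 for the hatching gland, 0.0527 for pituitary hormones, 0.111 for pigment cells and 0.263 for photoreceptors. With slides as a block in addition, 9 of the 13 were called. Intestine (camera adjusted p = 0.0851), exocrine pancreas (0.0979), pituitary hormones (0.0556) and photoreceptors (0.301) were not. Lists called at 4 ppb without the array but not with it were PPAR targets and fatty acid oxidation (25 of 31 lower, median -0.10, camera adjusted p = 0.0176, estimated-correlation adjusted p = 0.545), lower on all 4 slides, and cell cycle (47 of 58 lower, camera adjusted p = 0.000630, estimated-correlation adjusted p = 0.781). The cell cycle median was -0.37 on slide 1 and 0.03, 0.02 and -0.01 on slides 2 to 4, so slide 1 alone carried it. Lens (33 of 55 higher, camera adjusted p = 5.17e-05, estimated-correlation adjusted p = 0.199) and epidermis genes (24 of 36 higher, camera adjusted p = 0.00725, estimated-correlation adjusted p = 0.529) were called as well, and under quantile normalization their medians went from 0.03 to 0.01 and from 0.03 to 0.00.

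Among single genes at 4 ppb, the lowest p among decreases belonged to klf9, a transcription factor induced by glucocorticoids and thyroid hormone, with a log2 difference of -1.45 (SE 0.51), lower on 4 of 4 slides. On slides 1 to 4 the klf9 log2 signal was -3.80, -1.86, -1.64 and -3.04 at 4 ppb. At 0 ppb it was -1.38, -1.59, -1.26 and -0.31, so slides 1 and 4 carried most of the difference. fkbp5, a glucocorticoid-induced co-chaperone, differed by -1.65 (SE 0.71), with -3.57 and -3.08 on slides 1 and 4, 0.22 and -0.18 on slides 2 and 3, and -1.10 without 4 ppb replicate 1. ucp3, a mitochondrial uncoupling protein, differed by -0.77 (SE 0.34), crp3 by -0.67 (SE 0.29), matn3a, a cartilage matrix protein, by -0.60 (SE 0.28), and ctsl.1 by -0.43 (SE 0.20). mmadhca (-0.40), cthl (-0.44) and ripk2 (-0.44) were lower on 4 of 4 slides. Higher values were found for hspbap1 (0.77, SE 0.34), fam53c (0.45, SE 0.22), scinlb (0.44, SE 0.24), bnip3lb (0.36, SE 0.19), nbeaa (0.36, SE 0.20), pip5k1ca (0.34, SE 0.19) and mpp1 (0.31, SE 0.17), each on 4 of 4 slides. phactr3b (0.50, SE 0.27; 0.29 without 0 ppb replicate 3), prom1b (0.37, SE 0.21) and enpp4 (1.38, SE 0.78; 0.92 without 4 ppb replicate 1) completed the set; enpp4 was higher on only 2 of 4 slides and above background on 3 of 4 arrays, and 10 of 17 probes of mpp1 were higher. None of these passed the test (limma adjusted p = 1.00 each).

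At 4 ppb limma called 0 of 107040 probes, and 31 had an unadjusted p under 0.05 (5 higher, 26 lower). Chance alone would give about 5352 if the shared spread suited the unchanged probes. Here the median residual SD was 0.646, against 0.182 without the 40 ppb replicate 1 array and with slides as a block. The low count therefore does not show fewer differences than chance. Leaving out the 40 ppb replicate 1 array and taking slides as a block also gave 0 calls, with 5518 probes under 0.05. Adjusted over the list alone, 0 members of any list passed with all 16 arrays. The number of lists called was 13, and it was 8 without 0 ppb replicate 1 and 4 without 0 ppb replicate 2. With each of the 8 arrays left out in turn, the xenobiotic and photoreceptor lists were called 4 times and the erythroid and pituitary lists 3 times.

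**Figure D2:**
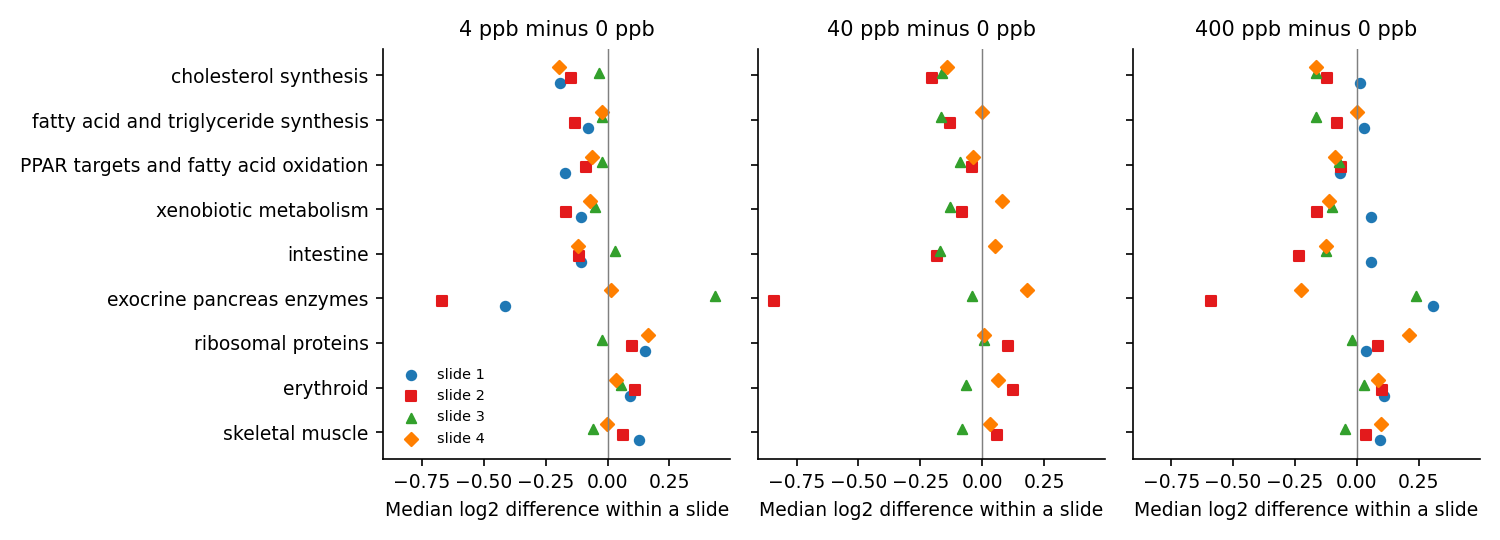
Median log2 difference from 0 ppb of 9 gene lists within each slide, for 4, 40 and 400 ppb, 1 symbol per slide; slide 1 is left out at 40 ppb because it holds the 40 ppb replicate 1 array. Cholesterol synthesis lies below 0 on all 4 slides at 4 ppb, and exocrine pancreas enzymes range from -0.67 to 0.43 there; the ribosomal protein and skeletal muscle medians at 4 ppb change sign under quantile normalization.

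In the comparison of 40 ppb with 0 ppb, the 40 ppb replicate 1 array set most of the values. Values given without that array compare 40 ppb replicates 2 to 4 with all 4 controls, unless slides are taken as a block. The slide 1 control then has no partner, so differences between slides can enter these values. Without that array, 21 of 25 cholesterol synthesis genes were lower (median -0.10, camera adjusted p = 0.00867, estimated-correlation adjusted p = 0.692). They included hmgcra, the rate-limiting reductase of the pathway, at -0.27, and sc5d at -0.20. Intestinal genes were lower in 24 of 30 cases (median -0.15, camera adjusted p = 0.000170, estimated-correlation adjusted p = 0.692), with the glucose transporter slc5a1 at -0.53. Photoreceptor genes were lower in 49 of 57 cases (median -0.19, camera adjusted p = 1.52e-05, estimated-correlation adjusted p = 0.692), with grk1b, an opsin kinase, at -0.46 and guca1c at -0.51. Fatty acid and triglyceride synthesis genes were lower in 18 of 20 cases (median -0.10, camera adjusted p = 0.00582, estimated-correlation adjusted p = 0.360). In the planned fit with all arrays the photoreceptor list was called, but the cholesterol, intestinal and fatty acid lists were not. On slide 4 the median of the intestinal list was 0.05, against -0.18 and -0.17 on slides 2 and 3. The photoreceptor median was -0.02 there (-0.35 and -0.35 on slides 2 and 3), and that of fatty acid synthesis 0.00 (-0.13 and -0.17), so these differences rest on slides 2 and 3.

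Without that array, further lists were lower at 40 ppb: glycolysis (34 of 43, camera adjusted p = 0.00167), oxidative phosphorylation (54 of 73, camera adjusted p = 0.00845), Nrf2 and antioxidant genes (25 of 33, camera adjusted p = 0.0162), exocrine pancreas (17 of 21, camera adjusted p = 0.0306), bile acid genes (10 of 12, camera adjusted p = 0.0317) and the glucocorticoid axis (16 of 21, camera adjusted p = 0.0317). Ribosomal proteins (72 of 79, camera adjusted p = 1.18e-06), erythroid (21 of 32, camera adjusted p = 0.0306) and lens genes (35 of 55, camera adjusted p = 0.0317) were higher. Their estimated-correlation adjusted p lay between 0.692 and 0.790. With all arrays the bile acid, exocrine pancreas, erythroid, lens and glucocorticoid axis lists were not called. For the bile acid, exocrine pancreas and erythroid lists the sign of the test also differed from that of the median or mean. With slides as a block in addition, glycolysis (camera adjusted p = 0.120), Nrf2 and antioxidant genes (0.0864), bile acid genes (0.112), the glucocorticoid axis (0.146), erythroid (0.0864) and lens genes (0.164) were not called. On slides 2, 3 and 4 the median was -0.84, -0.04 and 0.18 for exocrine pancreas, -0.03, -0.17 and 0.00 for oxidative phosphorylation, -0.06, -0.12 and 0.03 for glycolysis and 0.04, 0.00 and -0.01 for lens. Under quantile normalization without the array, the ribosomal median went from 0.07 to -0.01 and the lens median from 0.04 to 0.00.

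With all 16 arrays, 16 lists were called at 40 ppb, 11 lower and 5 higher, and the median of all tested probes lay 0.25 above 0 ppb. Oxidative phosphorylation genes were lower in 73 of 73 cases (median -0.78, camera adjusted p = 1.51e-06, estimated-correlation adjusted p = 0.966) and ribosomal protein genes in 79 of 79 (median -0.71, camera adjusted p = 4.12e-05, estimated-correlation adjusted p = 0.966). On slide 1 these medians were -2.92 and -2.98, and on the other slides they lay between -0.17 and 0.10. Under quantile normalization the medians over all slides were -0.07 and -0.02. Of the 16 lists, 4 were called in the same direction without the array and 1, the ribosomal proteins, in the opposite one. Cell cycle (58 of 58 lower; camera adjusted p = 0.539 without the array), skeletal muscle (54 of 58 lower; 0.317) and epidermis (34 of 36 lower; 0.969) were among those not called without it. Estrogen and androgen genes (27 of 32 higher; 0.694 without the array) were not called without it either, and their median of 0.44 became -0.42 under quantile normalization.

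Among single genes at 40 ppb, ucp3 had the smallest p of all named decreases, at -1.35 (SE 0.35) and -1.13 without the replicate 1 array, lower on 4 of 4 slides. lpin1a differed by -0.98 (SE 0.28) and by -0.65 without that array, though 2 of its 4 probes pointed the other way with that array and 0 without it. fkbp5 differed by -2.76 (SE 0.91; -1.75 without the array), pfkfb4b, a regulator of glycolysis, by -1.39 (SE 0.45; -0.79) and the collagen gene col9a1b by -1.27 (SE 0.43; -0.79). The ucp3, lpin1a and fkbp5 values at 40 ppb came from other probes than at 4 and 400 ppb, so their sizes cannot be compared across doses. On the fkbp5 probe used at 4 and 400 ppb, the mean log2 signal was 0.599 at 0 ppb. It was -1.115 at 40 ppb, and -1.106 without the array. oaz2b (-0.86; -0.60), slc25a43 (-0.89; -0.56), tppp3 (-0.88; -0.70), plbd2 (-0.74; -0.54) and stk35 (-0.76; -0.53) were lower on 4 of 4 slides, but without the array only 3 of 9 probes of plbd2 were lower. klf9 differed by -0.78 (SE 0.51), by -1.17 without the array and by -0.51 without 0 ppb replicate 4. The ribosomal gene rpl13a and the oxidase subunit cox7a1 stood at -0.82 (SE 0.48) and -0.78 (SE 0.37), and at -0.12 and -0.52 without the array.

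Of the 10 genes named here as highest at 40 ppb, 7 were near background in the controls. The gonadal transcription factor dmrt1 stood at 3.07 (SE 0.91; 1.96 without the array) and ccdc57 at 3.08 (SE 0.86; 2.02), each above background on 1 of 4 control arrays. erbb4a stood at least 3.37 above the controls on the log2 scale (2.04 without the array), the T-box factor eomesb at least 3.14 (1.80) and b3gnt3.2 at least 3.02 (1.53), with 0 of 4 control arrays above background. Without replicates 1 and 4, a choice made after the values were seen, these bounds were 1.23, 1.33 and 0.91, with 2, 1 and 1 of the 2 remaining arrays above background. sytl1 (3.45; 2.09) and usp6nl (2.90; 1.68) were above background on 1 of 4 control arrays, and replicate 4 made up most of what was left without replicate 1. On slides 2, 3 and 4 sytl1 differed by 0.74, 0.19 and 4.94, and usp6nl by 0.04, 1.38 and 3.4. dmrt1 differed there by 0.56, 3.68 and 1.39, and ccdc57 by 2.79, 1.75 and 2.02. zbtb24 (2.29; 1.27) and nos2b (2.21; 1.11) were above background on 4 of 4 control arrays and p2rx3b (2.31; 1.32) on 3. On slides 2, 3 and 4 zbtb24 differed by 0.67, 1.59 and 1.5, nos2b by 0.22, 1.43 and 1.80, and p2rx3b by 0.32, 1.19 and 2.24, though without the array only 1 of 3 probes of p2rx3b was higher. None of the named genes passed the test (limma adjusted p = 0.446 each).

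At 40 ppb limma called 0 probes, and 3513 had an unadjusted p under 0.05 (3235 higher, 278 lower). Without the replicate 1 array it also called 0, with 1712 under 0.05, and with slides as a block in addition 0, with 4725.

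The comparison of 400 ppb with 0 ppb asked about the highest dose. Cholesterol synthesis genes were lower in 22 of 25 cases (median -0.11, camera adjusted p = 0.00107, estimated-correlation adjusted p = 0.938). Members with the smallest p were insig1, a sensor of the sterol pathway (-0.24, SE 0.18), and sc5d (-0.32, SE 0.33). Fatty acid and triglyceride synthesis genes were lower in 13 of 20 cases (median -0.05, camera adjusted p = 0.000271, estimated-correlation adjusted p = 0.511). Xenobiotic metabolism genes were lower in 28 of 37 cases (median -0.08, camera adjusted p = 0.0289, estimated-correlation adjusted p = 0.938), with ugt5a1 at -0.78 (SE 0.66). Intestinal genes were lower in 22 of 30 cases (median -0.09, camera adjusted p = 0.000525, estimated-correlation adjusted p = 0.511), with slc5a1 at -0.38 (SE 0.30; -0.24 without 400 ppb replicate 4). Exocrine pancreas genes were lower in 18 of 21 cases (median -0.11, camera adjusted p = 0.0191, estimated-correlation adjusted p = 0.938). Their median was 0.31, -0.59, 0.24 and -0.22 on slides 1 to 4, and without the 40 ppb replicate 1 array the list was not called (camera adjusted p = 0.0852). The cholesterol, fatty acid, xenobiotic and intestinal lists each had a lower median on 3 of 4 slides, with slide 1 the exception. The 400 ppb array of slide 1 had 2491 outlier-flagged spots, against at most 325 on any other array. With normexp the xenobiotic and intestinal medians were -0.03 and -0.05.

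Erythroid genes were higher in 24 of 32 cases at 400 ppb (median 0.07, camera adjusted p = 0.0191, estimated-correlation adjusted p = 0.938) and on all 4 slides, with the globin hbbe3 at 0.59 (SE 0.59; 0.34 without 0 ppb replicate 3) and the heme enzyme alas2 at 0.29 (SE 0.47; 0.17 without 0 ppb replicate 2). Ribosomal protein genes were higher in 73 of 79 cases (median 0.07, camera adjusted p = 0.0302, estimated-correlation adjusted p = 0.998), with rps2 at 0.20 (SE 0.54). Their median was 0.04 with normexp and 0.006 with quantile normalization, and with slides as a block the list was not called (camera adjusted p = 0.0539). PPAR targets and fatty acid oxidation genes, the group that perfluoroalkyl acids are known to induce in rodent liver, were lower in 23 of 31 cases (median -0.07) and on all 4 slides. That list was not called with all arrays (camera adjusted p = 0.0642), and was called without the 40 ppb replicate 1 array (camera adjusted p = 0.00652, estimated-correlation adjusted p = 0.582). Skeletal muscle genes too were called without it and not with all arrays (44 of 58 higher, camera adjusted p = 0.00421, estimated-correlation adjusted p = 0.582), with a median of 0.05 that was 0.01 under quantile normalization. In the PPAR list, ucp3 differed by -0.83 (SE 0.34).

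Among single genes at 400 ppb, klf9 was at -1.57 (SE 0.51), fkbp5 at -2.09 (SE 0.71) and lpin1a at -0.58 (SE 0.21), each lower on 4 of 4 slides and by every tested probe of the gene. The ammonium transporter gene rhcga was at -2.10 (SE 0.78) and was above background on 2 of 4 arrays at this dose. zp3a.2, an egg coat protein, was at -0.76 (SE 0.27), enpp6 at -0.66 (SE 0.22), cremb, of the CREM repressor family, at -0.56 (SE 0.20), mmadhca at -0.54 (SE 0.20), cthl at -0.53 (SE 0.20) and the calcitonin gene calca at -0.42 (SE 0.17). egln3, a prolyl hydroxylase of the hypoxia response, had the smallest p among increases, at 0.90 (SE 0.33), and p4ha1b, a collagen prolyl hydroxylase, was at 0.58 (SE 0.27). pth1a, a parathyroid hormone, was at 1.25 (SE 0.65) and synprb at 1.97 (SE 0.97), the latter above background on 1 of 4 control arrays and at 1.13 without 400 ppb replicate 3. pip5k1ca (0.44), kat6a (0.41), osgn1 (0.46), nbeaa (0.36) and fam53c (0.43) were higher on 4 of 4 slides, and hspbap1 (0.68) on 3. The values of mmadhca, nbeaa and fam53c came from other probes than at 4 ppb. Without 400 ppb replicate 1, pip5k1ca was at 0.29, kat6a at 0.24 and osgn1 at 0.30. None passed the test (limma adjusted p = 1.00 each).

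At 400 ppb limma called 0 probes, and 77 had an unadjusted p under 0.05 (12 higher, 65 lower). It also called 0 without the 40 ppb replicate 1 array and with slides as a block, with 4917 under 0.05. Adjusted over the list alone, 0 members of any list passed with all arrays. The number of lists called was 7, and it was 13 without 400 ppb replicate 1, 3 without 400 ppb replicate 2, 4 without 400 ppb replicate 4, 4 without 0 ppb replicate 2 and 11 without 0 ppb replicate 4. With each of the 8 arrays left out in turn, the xenobiotic list was called 4 times and the erythroid and ribosomal lists 3 times.

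**Figure D3:**
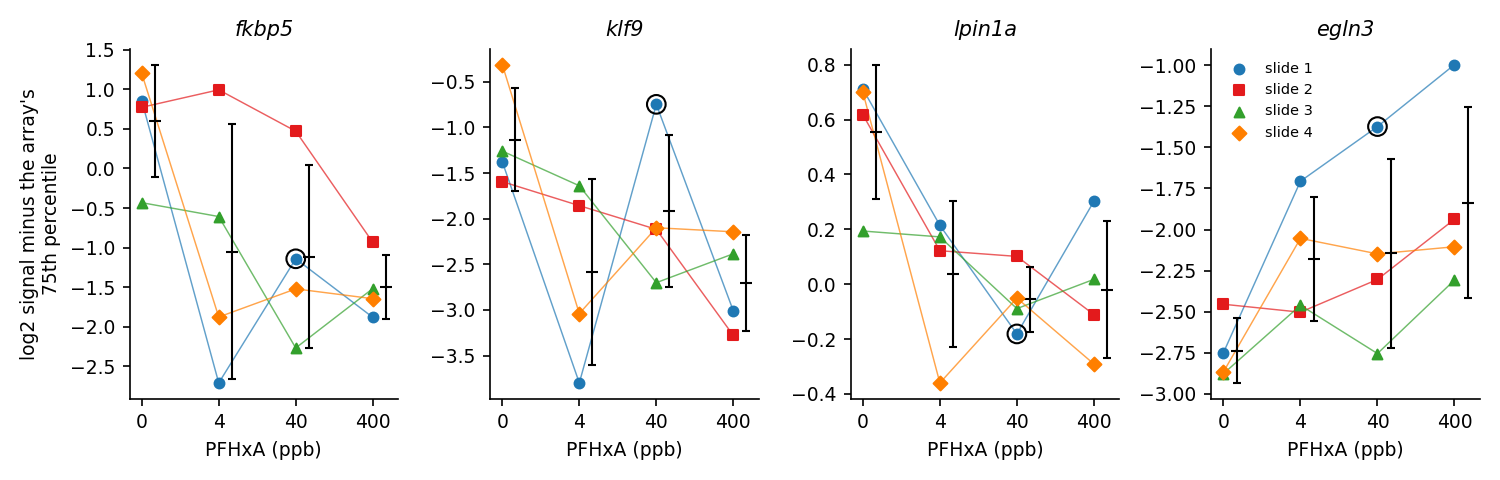
Log2 signal minus the array's 75th percentile of fkbp5, klf9, lpin1a and egln3 by PFHxA dose (ppb), 1 symbol and line per slide, with the mean and SD of the 4 replicates in black; the 40 ppb replicate 1 array is circled. At 400 ppb fkbp5 lies below 0 ppb on 4 of 4 slides, by 2.09 on average on the log2 scale.

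Across the ranked doses, egln3 had a slope of 0.27 per dose step (SE 0.10), pth1a 0.45 (SE 0.21), hif1an, an asparaginyl hydroxylase of the hypoxia response, 0.13 (SE 0.06), synprb 0.65 (SE 0.29) and pip5k1ca 0.12 (SE 0.06). fkbp5 had a slope of -0.63 (SE 0.23), cremb -0.19 (SE 0.06), enpp6 -0.18 (SE 0.07), lpin1a -0.18 (SE 0.07) and mmadhca -0.17 (SE 0.06). None passed the test of a trend (limma adjusted p = 1.00), which called 0 probes with 83 at an unadjusted p under 0.05. For any dose against 0 ppb the smallest p belonged to dmrt1, ccdc57, sytl1, ucp3 and eomesb (limma adjusted p = 0.872), again with 0 calls and with 440 under 0.05. Between doses limma called 0 probes as well: 3750 were under 0.05 for 40 against 4 ppb, 10 for 400 against 4 ppb and 4354 for 400 against 40 ppb.

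Fold changes were compared across probes, which are not independent replicates. Those at 4 and 400 ppb correlated with r = 0.524, against 0.501 in simulated groups without any effect that share the same controls. With controls and dosed arrays taken from different slides the mean r was 0.06. For 4 and 40 ppb r was -0.02 and for 40 and 400 ppb 0.03, and without the 40 ppb replicate 1 array 0.359 and 0.325, against 0.462 and 0.463 in the simulation. In every pair the covariance of the fold changes was below that of the simulation, with 0.0263 against 0.0281 for 4 and 400 ppb.

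The authors' deposited table for 4 ppb lists 36 probes, 13 higher and 23 lower, that for 40 ppb 121, with 102 higher and 19 lower, and that for 400 ppb 57, with 12 higher and 45 lower. The lowest of the KLF9 probes stands at -1.45 in the authors' deposited table for 4 ppb, at -1.17 for 40 ppb and at -1.60 for 400 ppb. RHCG stands at -1.56, -1.87 and -2.20 in the authors' deposited table, and UCP3 at -1.13 for 40 ppb. In the authors' deposited table EGLN3 is at 0.89 for 400 ppb. The largest increase at 40 ppb in the authors' deposited table is MEP1B, a metalloprotease, at 3.04. Of the probes in the authors' deposited table, 19, 60 and 34 matched a named probe within 0.01 on the log2 scale. For 40 ppb, 60 probes of the authors' deposited table matched when the replicate 1 array was left out, and 3 with it. Of the matched probes of the authors' deposited table, 4, 26 and 10 had an unadjusted p under 0.05 in the same direction in limma, and 0 passed adjustment. Matched probes that failed the background filter were not tested and count as not passing. Of the 43 matched increases of the authors' deposited table at 40 ppb, 22 were tested, and these 22 lay in the dimmest 8 of 20 brightness bins. The lists were chosen on the same arrays, so the counts from the authors' deposited table are not independent evidence.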

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

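Written before their results were seen were the tests of an added background, of a response to 40 ppb and of a signal of 40 ppb replicate 4 alone. The tests of negative controls, of an exchange of arrays, of the ranking of dim probes, of the time of day, of the probes per gene, of array position and of the splits of the arrays were chosen after the results were seen.

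The 40 ppb replicate 1 array had a median negative-control signal of 1317 scanner units (others at its dose 29.5 to 57), a mean net negative-control signal of 1321 (20.4 to 48.3 on the other arrays) and a median processed signal of 3658 (others at its dose 143 to 222). Its highest correlation with any other array was 0.609. Exchanged labels would leave this value as it is, so it cannot tell whether the array was exchanged with another of the series. The correlation of its differences with the mean of those of 40 ppb replicates 2 and 3 was -0.12. How far the differences of replicates 2 and 3 resemble each other was not tested. Without that reference, the value cannot tell whether replicate 1 shared a response with them. That test also left out 40 ppb replicate 4, the array that correlated best with replicate 1. A response to 40 ppb shared by replicate 1 and any other replicate therefore stays open. A constant added background would be removed by subtraction, yet after subtracting the negative-control median the median correlation of replicate 1 was 0.547 (0.542 before). Nonspecific signal from hybridisation or washing is a candidate cause, since negative controls match no zebrafish transcript and their median was 23.1 times the highest of the other arrays. What produced such a signal stays open, and so does whether this pool of fish differed.

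The increases at 40 ppb in the authors' deposited table were matched to 43 probes, whose median difference from the control of the same slide was 0.59 on replicate 2, 0.44 on replicate 3 and 1.46 on replicate 4. Over 42349 dim probes, the deviations of the 40 ppb replicate 4 array ranked like those of replicate 1, with a rank correlation of 0.543 (at most 0.108 in size on the other 14 arrays). Nonspecific signal on replicate 4, weaker than on replicate 1, may therefore have added to these increases. Both arrays had the same dose and slide position, so their likeness cannot tell such a signal from an effect of either. That replicate 4 alone made these increases cannot be told apart from a shared increase. The median within slides 2 and 3 was 0.63, above the bound of 0.4 set beforehand against this explanation. That bound was wrong, because the authors' means include slides 2 and 3, so the probes were picked to be high there; this reading, and the widening from 22 to 43 probes, came after the value was seen.

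fkbp5, klf9 and lpin1a were lower in the dosed groups, by a median of 1.57 on the log2 scale at 400 ppb (-1.57). A different time of day at sampling is argued against by the circadian clock list, whose median absolute change at 400 ppb was 0.0625 (largest 0.37, for hlfb), and a faulty probe by the probes of these genes, of which 100 percent (11 of 11) were lower. Array position stays open, since 0 doses were placed at more than 1 position, so dose and position cannot be told apart. The differences at every dose use the same 0 ppb arrays, so high controls would lower these genes at all doses. For klf9, 0 ppb replicate 4 had a log2 signal of -0.31, against -1.26 to -1.59 in the other controls. Lower values at several doses are therefore not repeated evidence. An effect of PFHxA on these 3 genes, which were picked because they were lower at several doses, did not pass the test at any dose (limma adjusted p = 1.00 at 400 ppb) and stays a hypothesis. The glucocorticoid axis list, which includes fkbp5 and klf9, was not called at 40 ppb with all arrays. It was called there without the replicate 1 array (camera adjusted p = 0.0317, estimated-correlation adjusted p = 0.692; 0.146 with slides as a block). The list was not called at 4 ppb (median -0.02, camera adjusted p = 0.153) or 400 ppb (median 0.0004 and mean -0.18, camera adjusted p = 0.211; slide 1 at 0.23).

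In limma all 8 tests called 0 probes (31, 3513 and 77 had an unadjusted p under 0.05 at 4, 40 and 400 ppb), and the highest other split also called 0. With a real count of 0 every split gives as many (35 of 35 for each of the 6 pairs of doses, 100 of 100 for any dose and for the trend), so these splits say nothing about chance. For gene lists the real and the highest other split called 13 and 11 at 4 ppb (1 of 35 splits as large), 16 and 19 at 40 ppb (11 of 35) and 7 and 20 at 400 ppb (17 of 35). Without the 40 ppb replicate 1 array these counts were 10 and 13 at 4 ppb (7 of 35), 13 and 12 at 40 ppb (1 of 35) and 8 and 15 at 400 ppb (14 of 35). The 35 splits ignore that the doses are paired by slide. Only 8 of them put 1 array of each slide pair on each side, too few for a share under 0.05. Of these 8, 1 gave as many lists at 4 ppb, 4 at 40 ppb and 5 at 400 ppb, and without the array 2, 1 and 4. With slides as a block the lists called were 13, 14 and 6, and without the array 14, 8 and 8. Splits that call far more lists than the real one point to a structure of the samples, and the slides are such a structure.

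Samples far from the other 3 of their group were found in 11 of 164 gene groups and 3 of 12 array measures, and chance gives about 1 in 20. The 40 ppb replicate 1 array accounted for 5 of the 11. Its log2 signals were -1.89 for lpin1a, -1.13 for hmgcra, 0.65 for cox7a1, 0.11 for grk1b and 5.11 for rpl13a. The 400 ppb replicate 1 array had 2491 outlier-flagged spots, which were left out, against 83 to 325 on the other arrays. That measure was not among those tested. The array weight of 400 ppb replicate 1 was 0.60, the lowest after that of 40 ppb replicate 1. At 400 ppb replicate 1 stood apart for pip5k1ca (-0.89) and fam53c (-0.64), and replicate 2 for the share of spots well above background (83.9%, others of its dose 75.5% to 76.3%). Every array of slide 2 had a share between 83.3% and 86.3%, so this value goes with the slide and not with the sample alone. At 4 ppb replicate 4 stood apart for lpin1a (-0.36) and srl (2.21). At 0 ppb replicate 3 stood apart for p4ha1b (1.68) and replicate 4 for cremb (-1.89).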

How the results depend on the processing

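The fits without the 40 ppb replicate 1 array beyond the planned leave-one-out, and the replicate block without it or without 40 ppb replicates 1 and 4, were chosen after the data were seen; the other alternatives were fixed before the data were examined. The count of 0 called probes was kept in all 8 tests under every alternative that keeps limma's adjusted p, including each array left out. An unadjusted p under 0.05 with a 1.5-fold change instead gave 19, 3396 and 50 probes at 4, 40 and 400 ppb, 3727, 7 and 4292 between doses, 434 for any dose and 48 for the trend, by dropping the adjustment. All 88 named gene values kept their direction under normexp, quantile normalization, the replicate block, array weights and each array left out; the variance model cannot move a fold. Gene lists called fell to 0 at each dose with an estimated correlation, with fry, and with the estimated correlation in the block without the replicate 1 array. At 40 ppb quantile normalization gave 0 lists and the block without that array 8, and at 400 ppb array weights gave 11. Leaving out single arrays gave 4 to 15 lists at 4 ppb, 13 to 17 at 40 ppb and 3 to 13 at 400 ppb. The correlation of fold changes at 4 and 40 ppb turned positive with normexp (0.367), quantile normalization (0.125), no filter (0.158), the filter on all arrays (0.0555), array weights (0.282) and the blocks without 1 (0.369) or 2 arrays (0.514), and ranged from -0.241 to 0.421 with single arrays left out. At 40 and 400 ppb it was 0.561 with normexp, 0.209 with no filter, 0.382 with array weights and 0.417 and 0.479 with those blocks, and ranged from -0.233 to 0.437. At 4 and 400 ppb it ranged from 0.304 to 0.736. Of the matched probes of the authors' deposited table at 4 ppb, 2 had an unadjusted p under 0.05 with normexp, 2 with the replicate block, 14 with array weights, 13 with the compared groups alone, 14 without the replicate 1 array and 13 and 13 with the blocks without 1 or 2 arrays (0 to 5 with single arrays left out). At 40 ppb these counts were 45 with no filter, 16 with the filter on all arrays and 11 with the compared groups alone (21 to 35 with single arrays left out). At 400 ppb they were 6 with quantile normalization, 26 with array weights, 25 with the compared groups alone, 25 without the replicate 1 array, and 25 and 26 with the blocks (5 to 8 with single arrays left out). Leaving out the 40 ppb replicate 1 array lowered the median shared spread from 0.646 to 0.292 (log2), and for the other settings the cause was not tested. Probes near background limit the 40 ppb increases: erbb4a, eomesb and b3gnt3.2 were above background on 0 of 4 control arrays.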

Other observations

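The slides were compared, and the genes below were chosen, after the data were seen; these tests had no plan. With the 40 ppb replicate 1 array left out and dose in the model, limma called 57265 of 107040 probes (53.5%) for slide, against 0 for any dose in the same kind of fit (4137 with an unadjusted p under 0.05). The clock genes chosen here were all among them except nr1d1 (limma adjusted p = 0.137) and nr1d2a (limma adjusted p = 0.238). The circadian clock list was not called on any slide (camera adjusted p between 0.103 and 0.766). Camera looks for a shift in a shared direction, so clock genes that move oppositely would cancel and this result cannot exclude a clock difference between slides. The median range of the list's genes over the slides was 0.45. The period gene per1a had a mean log2 signal of 1.75 on slide 1, 2.26 on slide 2, 1.02 on slide 3 and 0.29 on slide 4 (SD 0.08 to 0.14; limma adjusted p = 1.14e-06), while its largest dose difference was 0.14 in size. per2 ran from -0.62 on slide 2 to 0.52 on slide 3 (limma adjusted p = 1.4e-05), per3 from -1.42 on slide 4 to -0.50 on slide 2 (limma adjusted p = 9.7e-05), and bmal1b from 0.65 on slide 1 to 1.37 on slide 3 (limma adjusted p = 0.000671). fkbp5, klf9 and lpin1a were not called for slide (limma adjusted p = 0.0861, 0.328 and 0.199).

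Each slide differed from the rest in some gene groups, not only slide 2, which was read with the other software version. On slide 4 ribosomal protein genes were higher in 62 of 79 cases (median log2 0.05, camera adjusted p = 1.31e-06, estimated-correlation adjusted p = 0.953). On slide 2 lymphocyte genes were higher in 11 of 14 cases (median log2 0.66, camera adjusted p = 2.1e-05, estimated-correlation adjusted p = 0.897). Genes of estrogen, androgen and gonadal steroids were higher in 24 of 32 cases (median 0.35, camera adjusted p = 3.22e-06, estimated-correlation adjusted p = 0.188). Oxidative phosphorylation genes were higher in 7 of 73 cases (median -0.11, camera adjusted p = 0.000356, estimated-correlation adjusted p = 0.992). On slide 3 exocrine pancreas genes were higher in 20 of 21 cases (median 0.37, camera adjusted p = 0.0396, estimated-correlation adjusted p = 0.925). Slide, replicate pool and any day of work are the same division here, so these sources cannot be told apart.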
